A study of Rattus norvegicus with 16 samples.

How the data were processed

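The study measured RNA levels in the hearts of 16 rats aged 2 days on Affymetrix Rat Gene ST arrays. The rats belonged to the Hypertrophic Heart Rat (HHR), an inbred strain whose hearts are labelled hypertrophic, and the Normal Heart Rat (NHR), its control strain with hearts labelled normal. There were 4 groups of 4 arrays, namely HHR females, HHR males, NHR females and NHR males. Group and replicate number were taken from the sample titles. Each array held a single sample without pooling, per the labels' design text. The design text describes ventricles dissected from the atria, whereas a growth protocol in the labels speaks of the whole heart, so atrial tissue cannot be ruled out from the labels. RNA came from frozen tissue extracted with a miRNeasy kit, per the labels' protocols. Litters, dams and processing batches were not given in the sources used here.

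The values deposited by the authors are log2 expression values made with RMA, per the submitters' processing notes, which also name limma. RMA corrects background, normalizes between arrays and summarises the probes of each probe set on a log2 scale. Its version, probe annotation and any filter were not given in the sources used here. The deposited table held 27342 probe sets on 16 arrays, and every column of values was used. The medians of the arrays lay between 7.19 and 7.28. No background level was recorded beside them, so a dim probe set cannot be told from one without signal, and the number of arrays limits the precision of each mean.

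Probe sets were named from the platform's annotation table. A single gene symbol was listed for 15097 probe sets, several symbols for 323 and none for 11922, which are unnamed here. The named probe sets covered 14325 genes. Of the single-gene probe sets, 15067 matched a gene in the RefSeq table of assembly GRCr8, and 0 symbols had to be updated. That table was used only for names and for which genes neighbour each other. The genome build of the array's annotation was not given, so no coordinates are printed. The table included 198 probe sets whose values repeat those of another probe set exactly.

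Differences were tested with limma 3.58.1 in R 4.3.3. A mean per group was fitted to the log2 values of all 16 arrays, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over all 27342 probe sets, with a threshold of 0.05. There were 5 comparisons: HHR against NHR averaged over the sexes, the same within males and within females, the difference between those effects (the interaction), and males against females averaged over the strains. A log2 difference of HHR minus NHR is positive where HHR was higher. Errors beside differences are the model's moderated standard errors (SE).

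Before the data were examined, 24 gene lists were fixed from general knowledge: fetal and hypertrophy-associated, contractile and sarcomere, calcium handling and ion channel, cell cycle and DNA replication, fatty acid oxidation, oxidative phosphorylation, glycolysis, extracellular matrix and fibroblast, endothelial, mural cell, leukocyte, antigen presentation and interferon, erythroid, atrial, epicardial, neighbouring tissue, neurohormonal, growth factor, apoptosis and cell death, immediate early and heat shock, antioxidant and detoxification, cardiac transcription factor, genes earlier tied to rat heart mass or strain differences, and sex-linked genes. Lists with 5 or more measured members were tested with limma's camera, which compares a list with all other genes and was run with the inter-gene correlation preset at 0.01. Each gene was represented by its brightest probe set. Members were also counted past the threshold over all probe sets and adjusted over the list alone. Further lists were written after the first results had been seen and before they were tested: glucocorticoid-responsive genes, trabecular and conduction genes, S phase genes, and G2 and M phase genes.

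The genes named in the text follow a rule fixed at the same time. It took the 12 genes with the largest rise and the 12 with the largest fall in HHR among those past the threshold with the same sign in both sexes. It added up to 2 members of each list with the smallest adjusted p, and 8 genes whatever their values (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Trim55 and Endog). For the sex effect and the interaction it took up to 6 and up to 5 genes per direction. Other list members named as examples, and members of the later lists, were chosen after their values were seen.

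Each count of probe sets was recomputed with a filter on dim probe sets (above the 40th percentile of all values on at least 4 arrays), with single-gene probe sets only, after quantile normalization, median centring or cyclic loess on top of the deposited values, with trended and robust moderation, with array weights, with the replicate number as a block, without each array in turn, with a stricter threshold or a minimum of 1.5-fold, and, except for the interaction, with fewer covariates or arrays in the fit. The named genes were refitted under the filter, normalization, moderation, array weight, block and left-out array alternatives. The lists were tested again under the filter, normalization and block alternatives, with the probe set of smallest p per gene, with camera's correlation estimated per list and with fry, which asks whether a list's genes move on balance in 1 direction. A further alternative left out 3 NHR arrays and was chosen after seeing the data. So were the list tests without each array in turn. The closing section gives their effects.

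The fit was tested on simulated data with the real means and spreads of 27342 probe sets, of which 67, 67 and 66 were changed by 1.2-fold, 1.5-fold and 2-fold. For the strain effect, 46.3%, 97.0% and 100% of these were called in the right direction, and 2.99% of calls were false. In males 25.4%, 85.1% and 100% were called with 4.76% false, and in females 20.9%, 82.1% and 100% with 5.59% false. For the interaction the shares were 1.49%, 58.2% and 95.5% with 6.36% false, and for the sex effect 55.2%, 94.0% and 100% with 4.05% false. The simulated noise was independent between probe sets and had the same spread in every group. Correlation between genes, groups of unequal spread and arrays lying apart were not simulated, and few probe sets were changed. These shares therefore need not hold for the real arrays.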

Results

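Hearts of 2-day-old HHR and NHR pups were profiled on 16 arrays, with 4 females and 4 males of each strain. The arrays carried similar overall signal, with medians of 7.19 to 7.28 on the log2 scale, and any pair of arrays correlated at 0.990 or higher across probe sets. The first principal component held 34.2% of the variance, and all 8 HHR arrays lay on 1 side of the 8 NHR arrays along it. It also spread the NHR arrays, from -1.71 to 28.3, so its share of the variance is not that of strain alone. Replicates were tighter in HHR than in NHR: the median SD within a group was 0.0864 in HHR females and 0.0940 in HHR males, against 0.117 in NHR females and 0.123 in NHR males. Along the leading component of the variation within groups (26.7% of it), NHR female 3, NHR female 4 and NHR male 4 stood apart from the other NHR arrays, with scores of 14.4, 15.1 and 22.6 against values between -16.9 and 1.74. Those 3 arrays are called the NHR arrays apart in what follows. Leaving them out was an alternative chosen after seeing the data. It also lowers the power to call genes, and leaving out 3 other arrays was not run for comparison. Scores on the leading component within groups also followed the replicate number. In each of the 4 groups replicate 4 scored highest and replicate 3 next, and replicates 1 and 2 scored below 0. In HHR, female 4 scored 2.22 and male 4 scored 7.48. Processing batches were not given, so what the number stands for is open.

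**Figure D1:**
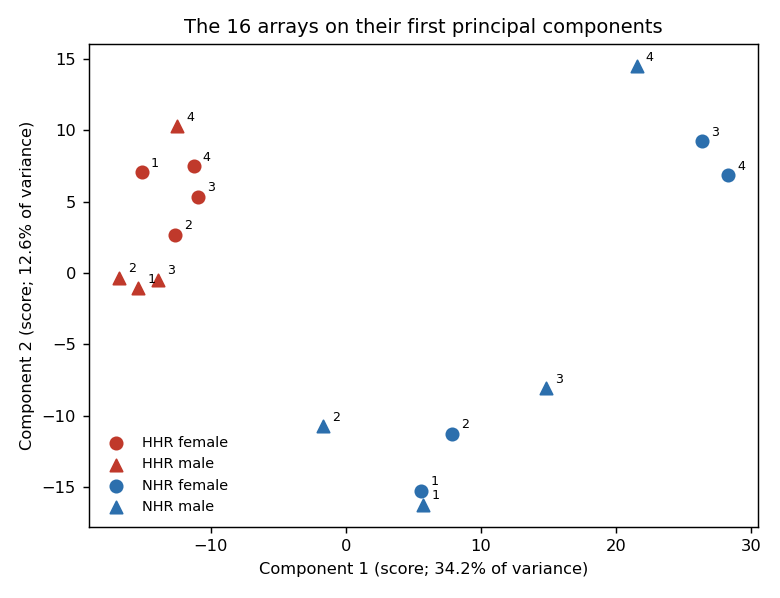
Scores of the 16 arrays on the first (34.2% of the variance) and second (12.6%) principal components of the log2 values, with the replicate number beside each point. The HHR arrays lie at -10.9 or below on the first component and the NHR arrays at -1.71 or above.

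The main comparison asked which transcripts differ between the hearts of the strain with inherited cardiac hypertrophy and those of its control strain. The largest rise was in Lcn2, which encodes lipocalin 2, a secreted iron-siderophore-binding protein of innate immunity. It averaged 9.30 ± 0.13 (SD, n = 8) in HHR and 6.96 ± 0.13 in NHR, a 5.05-fold difference (log2 difference 2.34, SE 0.06, limma adjusted p = 5.2e-14), and all 8 HHR arrays lay above the highest NHR array. Ankrd53, an ankyrin repeat gene, was 4.52-fold higher (log2 difference 2.18, SE 0.08, adjusted p = 6.2e-12). Htr2a, the serotonin 2A receptor, was higher by 1.67 (SE 0.10, adjusted p = 1.4e-08), and Med22, a subunit of the Mediator complex, by 1.62 (SE 0.05, adjusted p = 5.6e-13). The other genes among the 12 largest rises were Akr1b10 (an aldo-keto reductase, 1.49), Nt5c3a (a pyrimidine nucleotidase, 1.38), Itgbl1 (1.37), Wdr46 (a nucleolar protein, 1.34), Zfp347 (a zinc finger gene, 1.29), Pex3 (needed to form peroxisomes, 1.24), Serhl2 (1.19) and Bphl (a hydrolase, 1.07). In each of these 12 genes all 8 HHR arrays lay above every NHR array.

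The largest fall in HHR was in Trpm8, a cold-sensing cation channel. It averaged 5.54 ± 0.15 (SD, n = 8) in HHR and 7.04 ± 0.26 in NHR (log2 difference -1.49, SE 0.10, limma adjusted p = 3.1e-08), with all 8 HHR arrays below the lowest NHR array. Endog, which encodes a mitochondrial nuclease, fell by 1.23 (SE 0.08, adjusted p = 1.4e-08, 8 of 8 arrays). Pop5 (-1.28) and Rpph1 (-0.80), a protein subunit and the RNA of ribonuclease P, which trims the leader of transfer RNAs, were both lower in 8 of 8 HHR arrays. Further falls were in Akr1c14 (a hydroxysteroid dehydrogenase, -1.05), Car4 (a membrane-bound carbonic anhydrase, -1.05), Alox15 (a lipoxygenase, -1.04), Itga7 (a laminin-binding integrin of muscle, -0.92), Inka2 (-0.85) and Cxxc4 (an inhibitor of Wnt signalling, -0.85), each lower in 8 of 8 arrays. Rpl22, a ribosomal protein gene, differed by -0.99 (SE 0.23, adjusted p = 0.00566), and Plppr4 by -0.91 (SE 0.15, adjusted p = 4.5e-04), both with 6 of 8 HHR arrays below the lowest NHR array. Rpl22 was uneven within NHR (SD 0.71), its other 2 probe sets gave -0.80 and -0.83, and without the NHR arrays apart its difference was -0.50 (adjusted p = 0.0207, the highest of its 24 alternatives, whose lowest was 6.4e-04).

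**Figure D2:**
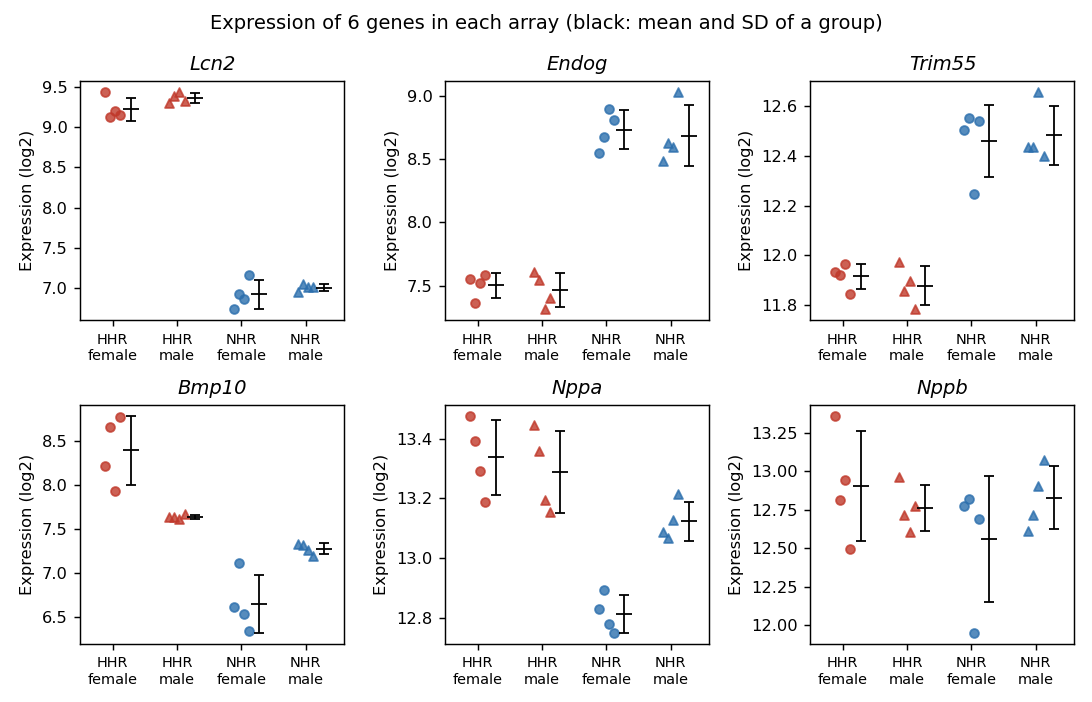
Log2 expression of Lcn2, Endog, Trim55, Bmp10, Nppa and Nppb on each of the 16 arrays by group, with 1 point per array and the mean ± SD of each group of 4 in black. Lcn2 (9.30 in HHR, 6.96 in NHR), Endog (7.49 and 8.71) and Trim55 (11.90 and 12.47) separate the strains in both sexes, whereas the strain difference of Nppb (0.14) lies within the spread of the arrays.

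Counted over the 27342 probe sets, 5651 (20.7%) passed the test for strain, 2636 of them higher and 3015 lower in HHR. They named 3355 genes. Most differences were small: the median size was 0.25, and 229 probe sets differed at least 1.5-fold (132 higher, 97 lower) and 37 at least 2-fold (21 higher, 16 lower). Centring each array on its median turned the balance of directions, from 46.6% of calls higher to 56.3% of 5229, so neither direction is given as the prevailing one. A probe set's signal can also change with a sequence variant under its probes, which the array cannot tell from a change in RNA level, and litter is not given in the sources used here, so litter and strain cannot be separated.

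Of 19 measured contractile and sarcomere genes, 12 fell in HHR, 0 rose and 7 did not pass (13 fell and 0 rose adjusted over the list alone). Trim55, a ubiquitin ligase bound to titin and microtubules of the sarcomere, fell by 0.57 (SE 0.05, limma adjusted p = 2.1e-06, 8 of 8 arrays). Its relative Trim63, which marks sarcomere proteins for degradation, fell by 0.31 (SE 0.04, adjusted p = 1.3e-04, 8 of 8 arrays). Mylk3, the cardiac myosin light chain kinase (-0.41), Mybpc3, a thick filament protein (-0.25), and titin, Ttn (-0.24), passed the test too. Myh6, the fast myosin heavy chain of adult rat ventricle, differed by -0.21 (SE 0.05, adjusted p = 0.00484, 7 of 8 arrays). Camera ranked the list below other genes (mean -0.17, adjusted p = 8.0e-05), a call not made with an estimated correlation (adjusted p = 0.562 with an estimated correlation; lowest over the alternatives 2.5e-09). The list moved with the NHR arrays apart: its mean loading on the component that sets them apart exceeded 99.8% of 10000 random lists of like expression, and without those arrays 7 genes were lower and 0 higher. The mean was then -0.15 and the camera call stayed (adjusted p = 1.4e-04).

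Ion channel and calcium handling genes were lower more often than higher. Among 27 measured genes 11 fell and 3 rose, with the same counts adjusted over the list alone. The T-type calcium channel gene Cacna1h fell by 0.43 (SE 0.06, limma adjusted p = 1.4e-04, 8 of 8 arrays), and the L-type channel Cacna1c (-0.28), the ryanodine receptor Ryr2 (-0.26) and the potassium channel Kcnq1 (-0.25) were lower. Kcnj5, a subunit of the acetylcholine-gated potassium channel, rose by 0.52 (SE 0.08, adjusted p = 3.6e-04, 8 of 8 arrays). Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.07 (SE 0.03, adjusted p = 0.137, 6 of 8 arrays below the lowest NHR array). After cyclic loess it passed, at -0.14 (adjusted p = 0.00804, within a range of 0.00804 to 0.333). The list test gave an adjusted p of 0.0462 (mean -0.07), and adjusted p = 0.638 with an estimated correlation, within a range of 5.2e-04 to 0.638 over the alternatives. Leaving out any of 9 arrays ended this call: the adjusted p was 0.0805 without HHR female 1, 0.0603 without HHR female 3, 0.0685 without HHR male 1, 0.0706 without HHR male 4, 0.0891 without NHR female 1, 0.0823 without NHR female 2 or NHR male 1, 0.0675 without NHR male 2 and 0.0556 without NHR male 3.

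Of 18 measured fetal and hypertrophy-associated genes 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.383, mean 0.05). Without the NHR arrays apart 3 were higher and 1 lower, with a mean of 0.02. Nppa, the atrial natriuretic peptide gene, averaged 13.31 ± 0.12 (SD, n = 8) in HHR and 12.97 ± 0.18 in NHR (difference 0.34, SE 0.05, limma adjusted p = 2.9e-04, 5 of 8 arrays above the highest NHR array). Fhl1, a LIM protein of the sarcomere, rose by 0.42 (SE 0.07, adjusted p = 7.9e-04, 8 of 8 arrays). The brain natriuretic peptide gene Nppb differed by 0.14 (SE 0.13, adjusted p = 0.485) with 1 HHR array above the highest NHR array, and skeletal alpha-actin, Acta1, by -0.02 (SE 0.04, adjusted p = 0.743; -0.09 after cyclic loess, adjusted p = 0.156, the lowest of its alternatives, whose highest was 0.989). Without NHR female 3, the Nppb difference was 0.04 (adjusted p = 0.842, the highest of its alternatives, whose lowest was 0.273). The slow myosin heavy chain Myh7 was lower, by -0.14 (SE 0.04, adjusted p = 0.0206, 4 of 8 arrays), and did not pass without the NHR arrays apart (-0.11, adjusted p = 0.103, the highest of its alternatives, whose lowest was 0.00234).

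Of 39 measured cell cycle and DNA replication genes, 10 rose in HHR, 1 fell and 28 did not pass (12 rose and 1 fell adjusted over the list alone). Ccne1, the cyclin that drives entry into S phase, rose by 0.60 (SE 0.08, limma adjusted p = 8.9e-05, 8 of 8 arrays), and Mcm5, a subunit of the replicative helicase, by 0.52 (SE 0.08, adjusted p = 2.4e-04, 8 of 8 arrays). Prim1, the primase (0.66), Mcm2 (0.39) and Cdc6, which loads the helicase (0.39), were higher, and the mitotic cyclin Ccnb2 (-0.26 and -0.28 on its 2 probe sets) was lower. The list test gave an adjusted p of 0.00234 (mean 0.13), and adjusted p = 0.778 with an estimated correlation, within a range of 3.1e-05 to 0.778. Fry did not call it (adjusted p = 0.209). The list's loading lay below all 10000 random lists (percentile 0), that is, lower in the NHR arrays apart. Without those arrays the mean was 0.05, and 5 of its genes were higher and 1 lower (adjusted p = 0.0536).

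Metabolic genes changed in both directions. Of 27 fatty acid oxidation genes 7 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.42). Without the NHR arrays apart 4 were higher and 2 lower (mean 0.02, against 0.04 with all arrays). Cd36, the fatty acid transporter, rose by 0.49 (SE 0.07, limma adjusted p = 9.3e-05, 8 of 8 arrays), and Etfa, a subunit of the electron transfer flavoprotein, by 0.44 (SE 0.06, adjusted p = 9.9e-05, 8 of 8 arrays). Lipoprotein lipase, Lpl, was lower (-0.40). Of 34 oxidative phosphorylation genes 7 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.275). Their mean loading exceeded all 10000 random lists (percentile 100), and without the NHR arrays apart the list passed, with 4 higher and 2 lower (mean 0.05, adjusted p = 0.00674, the lowest over its alternatives, whose highest was 0.853). Ndufa10, a complex I subunit, fell by 0.41 (SE 0.06, adjusted p = 1.7e-04, 8 of 8 arrays), and Sdhc, a complex II subunit, rose by 0.21 (SE 0.04, adjusted p = 0.00111, 7 of 8 arrays). Of 19 glycolysis genes 5 rose and 3 fell, as when adjusted over the list alone (adjusted p = 0.30). Pgam2, the muscle phosphoglycerate mutase, rose by 0.56 (SE 0.07, 8 of 8 arrays), and Slc2a1, the glucose transporter typical of fetal heart, fell by 0.48 (SE 0.07, 8 of 8 arrays).

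Among markers of other cells and tissues, camera ranked the epicardial and atrial lists above other genes. Of 10 epicardial markers 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0096, mean 0.18; adjusted p = 0.562 with an estimated correlation, lowest 0.00303). Aldh1a2, which makes retinoic acid, rose by 0.48 (SE 0.08, limma adjusted p = 8.5e-04, 7 of 8 arrays), and Gpm6a by 0.31 (SE 0.06, adjusted p = 0.00194, 5 of 8 arrays). Of 12 atrial markers 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0462, mean 0.19). The adjusted p was 0.667 with an estimated correlation, within a range of 0.0082 to 0.667, and the call was lost in 14 alternatives. Among these, the adjusted p was 0.133 without HHR female 2, 0.0637 without HHR male 2, 0.0706 without HHR male 4, 0.0891 without NHR female 1, 0.0650 without NHR female 2, 0.0503 without NHR female 4, 0.0541 without NHR male 1, 0.0675 without NHR male 2 and 0.0809 without NHR male 4. Bmp10, a growth factor of atrial and trabecular myocardium, rose by 1.05 (SE 0.11, adjusted p = 9.5e-06, 8 of 8 arrays), and the atrial potassium channel gene Kcnj3 by 0.57, whereas Kcna5, also an atrial potassium channel gene, was lower (-0.34). Sln and Myl7, abundant in atria, differed by 0.34 (adjusted p = 0.54) and 0.07 (adjusted p = 0.565). Without the NHR arrays apart, 3 atrial and 3 epicardial markers were higher and 0 of either lower, with means of 0.17 and 0.15. Both camera calls stayed (adjusted p = 0.0451 and 0.00895).

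Of 11 endothelial markers 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.155, fry adjusted p = 0.00257, range over the alternatives 0.00257 to 0.667). Camera did call the list after quantile normalization (adjusted p = 0.0233) or cyclic loess (adjusted p = 0.0208). Cldn5, a tight junction protein, fell by 0.41 (SE 0.05, limma adjusted p = 6.8e-05, 7 of 8 arrays), and the receptor Tie1 by 0.22 (SE 0.04, adjusted p = 0.00138, 8 of 8 arrays). The endothelial list's loading was above 99.3% of random lists, the leukocyte list's above 99.4% and the erythroid list's above 99.7%. These are means: 6 of 11 endothelial, 15 of 23 leukocyte and 12 of 15 erythroid markers had a loading in that direction. Random lists also ignore the correlation between genes. Without the NHR arrays apart, 5 endothelial markers were lower and 1 higher (mean -0.11, against -0.13 with all arrays). Leukocyte markers gave 1 higher and 1 lower of 23, also adjusted over the list alone (adjusted p = 0.508; without the NHR arrays apart 1 and 2, mean -0.02 against -0.04). The complement gene C1qb rose by 0.38 (SE 0.09, 3 of 8 arrays) and Ptprc, the pan-leukocyte phosphatase, fell by 0.27 (SE 0.05, 8 of 8 arrays). Of 15 erythroid markers 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.508; without the NHR arrays apart 4 and 2, mean 0.12 against 0.09). The beta-globin gene Hbb rose by 0.45 (SE 0.10, 5 of 8 arrays) and embryonic Hbe1 was higher (0.76), while Epb42, a red cell membrane protein, fell by 0.55 (SE 0.07, 8 of 8 arrays).

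Of 26 extracellular matrix and fibroblast genes 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.30). Timp2, an inhibitor of matrix metalloproteinases, rose by 0.32 (SE 0.06, limma adjusted p = 0.00175, 8 of 8 arrays), and the basement membrane collagen Col4a1 fell by 0.23 (SE 0.04, adjusted p = 0.00169, 4 of 8 arrays). Of 13 mural cell markers 2 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.56). Notch3 rose by 0.19 (SE 0.05, 6 of 8 arrays; not past the test without the NHR arrays apart) and Vtn fell by 0.29 (SE 0.07, 5 of 8 arrays). Neighbouring tissue markers gave 1 higher and 1 lower of 26, and 0 of either adjusted over the list alone (adjusted p = 0.786). Ttr, the thyroxine carrier, differed by 0.18 (adjusted p = 0.0442, 5 of 8 arrays) and Myog, a regulator of skeletal muscle, by -0.17 (adjusted p = 0.0311, 3 of 8 arrays). Ttr lost its call in 13 alternatives (adjusted p up to 0.0923), among them without any of HHR female 2, 3 or 4, the HHR males, NHR female 2 or NHR male 1, 3 or 4. Myog lost it in 11 (adjusted p up to 0.0828), among them without HHR female 1 or 4, HHR male 3 or 4, NHR female 4 or NHR male 1 or 3.

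Genes of the major histocompatibility complex and interferon response moved both ways. Of 26 measured, 1 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.30). Psmb9, an immunoproteasome subunit, rose by 0.82 (SE 0.09, limma adjusted p = 9.7e-06, 8 of 8 arrays). RT1-Da, a class II antigen-presenting chain, fell by 0.50 (SE 0.08, adjusted p = 3.4e-04, 8 of 8 arrays), and the interferon regulator Irf7 was lower (-0.52). These genes vary in sequence between strains, which bears on the limit of the probes given for the strain comparison.

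Among signalling genes, Bmp4, a morphogen of the developing heart, rose by 0.84 (SE 0.08, limma adjusted p = 4.7e-06, 8 of 8 arrays), and Nrg1, an endothelial ligand that signals to cardiomyocytes, by 0.79 (SE 0.10, adjusted p = 6.5e-05, 8 of 8 arrays). Erbb4, the receptor of Nrg1 (-0.30), and Igf1 (-0.31) were lower. The growth factor list had 3 higher and 2 lower of 30, also adjusted over the list alone (adjusted p = 0.30). Of 24 neurohormonal genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.987); the list's median (-0.03) and mean (-8.4e-04) lay below 0 and its camera test above. Endothelin 1, Edn1, a vasoconstrictor peptide, was higher by 0.67 (SE 0.11, adjusted p = 4.8e-04, 2 of 8 arrays above the highest NHR array), and Hsd11b1, which regenerates active glucocorticoid, by 0.27 (SE 0.06, adjusted p = 0.00252, 2 of 8 arrays).

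Of 25 apoptosis and cell death genes 4 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.30). Beside Endog, Casp12, a caspase of the endoplasmic reticulum, rose by 0.47 (SE 0.06, limma adjusted p = 3.9e-05, 8 of 8 arrays), and the survival gene Bcl2 was higher (0.72). Of 22 cardiac transcription factors 2 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.206). Hey2, a repressor of atrial genes in the ventricle, fell by 0.61 (SE 0.07, adjusted p = 3.7e-05, 8 of 8 arrays), and Hopx rose by 0.35 (SE 0.06, adjusted p = 4.9e-04, 8 of 8 arrays). Of 31 antioxidant and detoxification genes 7 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.483). Ephx1, an epoxide hydrolase, rose by 0.38 (SE 0.06, 8 of 8 arrays), and Gstt1, a glutathione transferase, fell by 0.32 (SE 0.05, 8 of 8 arrays). This list's loading was above 99.8% of random lists, and without the NHR arrays apart 1 gene was higher and 1 lower, while the mean was 0.04 against 0.02 with all arrays (neither called by camera). Of 20 immediate early and heat shock genes 3 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.936). Dusp1, a phosphatase of MAP kinases, rose by 0.52 (SE 0.08, 7 of 8 arrays), and Hspb1, a small heat shock protein, by 0.31 (SE 0.06, 7 of 8 arrays). The loading of this list was at percentile 0.03, and without the NHR arrays apart 2 were higher and 4 lower (mean -0.07, against -0.00205 with all arrays). Of 10 genes earlier tied to rat heart mass or strain differences, 2 rose (Nppa and Cd36) and 2 fell (Endog and Trim55), with 2 and 3 adjusted over the list alone (adjusted p = 0.30). Earlier work on these genes may have used the same strains, so this count is not independent evidence.

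**Figure D3:**
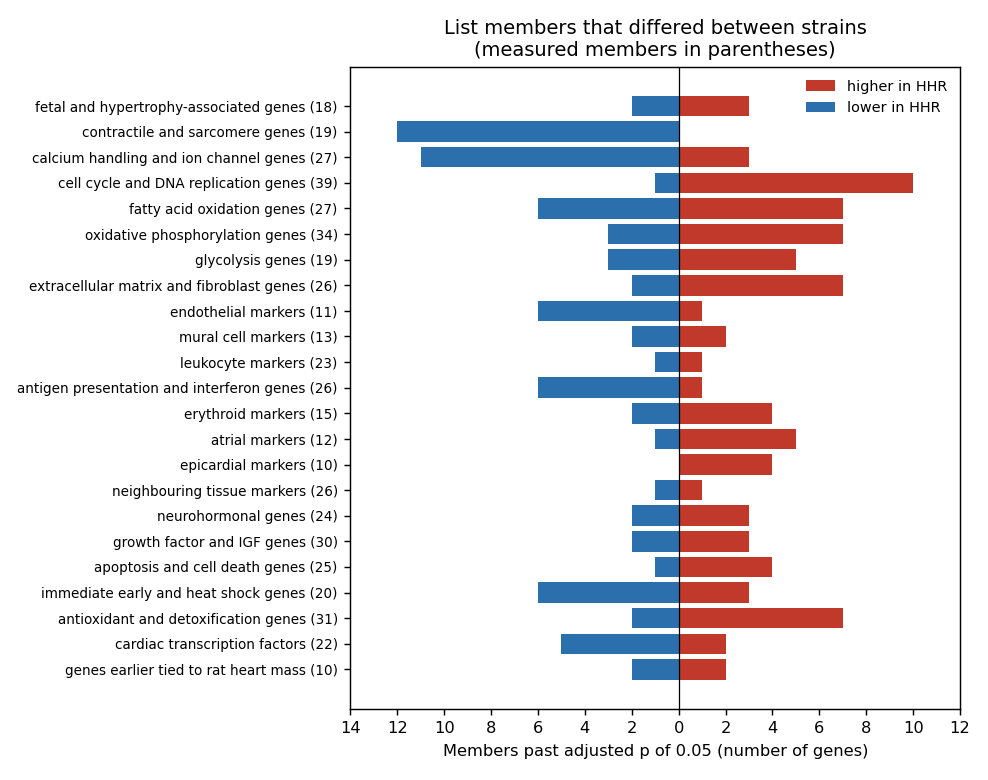
For each gene list, the number of measured members higher (right) and lower (left) in HHR past an adjusted p of 0.05 in the strain comparison. The contractile list has 0 higher and 12 lower, the cell cycle list 10 higher and 1 lower.

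Within males, Lcn2 was higher in HHR by 2.36 (SE 0.08, limma adjusted p = 1.6e-11, 4 of 4 arrays above the highest NHR male) and Ankrd53 by 2.25 (SE 0.11, adjusted p = 1.2e-09, 4 of 4 arrays). Trpm8 (-1.52), Pop5 (-1.47) and Endog (-1.22) were lower in 4 of 4 arrays. Of the contractile genes 4 fell and 0 rose in males (9 and 0 adjusted over the list alone; camera adjusted p = 2.0e-05, adjusted p = 0.479 with an estimated correlation). Of the calcium handling genes 3 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.0297, and adjusted p = 0.639 with an estimated correlation). Of the cell cycle genes 3 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 2.1e-05, and adjusted p = 0.817 with an estimated correlation). Bmp10 differed by 0.36 in males (adjusted p = 0.213) and Nppa by 0.16 (adjusted p = 0.236). In all, 1098 probe sets passed (556 higher, 542 lower). This count depended on single arrays: it was 589 without HHR male 1, 518 without HHR male 2, 722 without HHR male 4, 704 without NHR male 1, 2026 without NHR male 2, 489 without NHR male 3 and 689 without NHR male 4. With array weights it was 2035.

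In females, Bmp10 rose by 1.75 (SE 0.16, limma adjusted p = 4.6e-06) and Edn1 by 1.20 (SE 0.16, adjusted p = 2.0e-04), each with 4 of 4 HHR arrays above the highest NHR female. Nrg1 rose by 1.08 and Nppa by 0.52, beside Lcn2 (2.31) and Ankrd53 (2.10). Of the contractile genes 6 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.551 with an estimated correlation). Of the atrial markers 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00984, and adjusted p = 0.582 with an estimated correlation). Of the epicardial markers 3 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.00774, and adjusted p = 0.551 with an estimated correlation). In all, 3278 probe sets passed (1580 higher, 1698 lower), of which 48.2% were higher. After median centring it was 58.5% of 3034. The count was 2101 without HHR female 1, 2089 without NHR female 3, 1830 without NHR female 4 and 1238 without the NHR arrays apart. That last count rests on NHR female 1 and NHR female 2 as the only NHR females, so part of its fall can come from lower power.

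The strain differences of the sexes were then compared with each other. Across all probe sets the male and female effects correlated at r = 0.687 (Spearman's rho 0.597), although probe sets are not independent replicates. The sign was the same in both sexes for 71.4% of all probe sets. Called in both sexes were 767, all with the same sign, where 132 would be called in both if the calls were independent. Both effects share the same estimate of spread per probe set, which by itself can raise the number called in both. The 132 is therefore not a strict expectation. Within the sexes, the median, mean and camera test of a list differed in sign for 6 lists in males (fatty acid oxidation, oxidative phosphorylation, extracellular matrix, mural, neighbouring tissue and apoptosis) and for the neurohormonal list in females, none of them called.

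**Figure D4:**
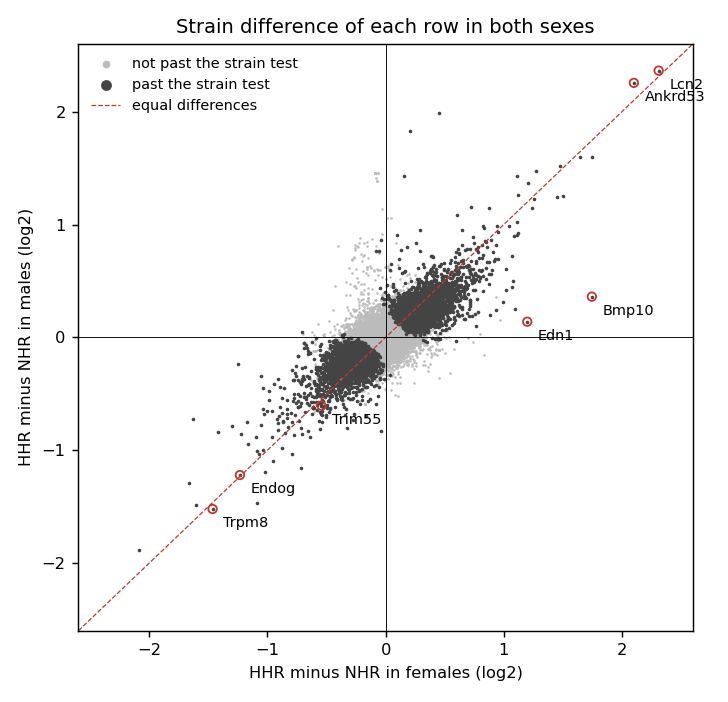
Strain difference (log2, HHR minus NHR) of each of the 27342 probe sets in females (horizontal) and males (vertical), with those past the test for strain in dark and 7 named genes circled. The effects of the sexes correlated at r = 0.687 over all probe sets and had the same sign for 71.4% of them. Bmp10 (0.36 in males, 1.75 in females) and Edn1 (0.14 and 1.20) lie below the line of equal effects.

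The interaction asked whether the strain difference itself differed between the sexes. Bmp10 came closest: its strain difference was smaller in males by -1.38 (SE 0.22), with group means of 8.39 ± 0.39 (SD, n = 4) in HHR females, 7.64 ± 0.03 in HHR males, 6.65 ± 0.33 in NHR females and 7.28 ± 0.06 in NHR males. Its adjusted p over all probe sets was 0.243, and 0 probe sets passed limma's test. At an unadjusted p under 0.05 there were 1390 (5.08%). Edn1 (-1.06, SE 0.22, adjusted p = 0.676) followed the same pattern, with group means of 9.10 in HHR females, 8.57 in HHR males, 7.91 in NHR females and 8.43 in NHR males. Bmp10 passed without HHR female 3 (adjusted p = 0.0174, difference in females 1.90) and without NHR female 2 (adjusted p = 0.0176), within a range of 0.0174 to 0.831 over its alternatives. Camera placed the fetal and hypertrophy list (mean -0.14, adjusted p = 2.3e-04) and the atrial list (mean -0.26, adjusted p = 0.00518) below other genes, that is, with the smaller strain difference in males; adjusted p = 0.688 with an estimated correlation for both. Of their members 0 passed over all probe sets, and 0 fetal and 2 atrial genes adjusted over the list alone. Median, mean and test differed in sign for 4 uncalled lists (contractile, erythroid, neurohormonal and cardiac transcription factors).

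Males and females were also compared over both strains. Pbdc1, a gene of the X chromosome, was higher in females (8.34 ± 0.18, SD, n = 8, against 7.91 ± 0.06 in males; log2 difference of males minus females -0.42, SE 0.06, limma adjusted p = 0.0105). Dio2, which activates thyroid hormone, was higher in males (5.28 ± 0.06 against 4.95 ± 0.10; difference 0.33, SE 0.04, adjusted p = 0.0105), at a level too dim to pass the filter. An unnamed probe set, 10936669, was higher in females by -0.39 for males minus females (SE 0.05, adjusted p = 0.0128). For each of these 3 all 8 arrays of 1 sex lay above every array of the other. They were the 3 that passed, and 1749 (6.40%) had an unadjusted p under 0.05. The unnamed one missed the threshold without HHR female 2 (adjusted p = 0.0507) or NHR male 3 (adjusted p = 0.0508, the highest without any 1 array; the lowest was 0.0165). Without the NHR arrays apart 0 passed, with adjusted p = 0.106 for Pbdc1 and 0.162 for Dio2, the highest of their alternatives, whose lowest were 0.00383 and 0.00803. Of the sex-linked list 2 genes were measured, too few to test. Ddx3x, an X-linked helicase, differed by -0.11 for males minus females at its brighter probe set (adjusted p = 0.777) and by -0.24 at the other (adjusted p = 0.354, 7 of 8 female arrays above the highest male array). Eif2s3, which rose in HHR by 0.43 (adjusted p = 0.00154, 4 of 8 arrays; 0.28 without the NHR arrays apart), differed between the sexes by -0.28 (adjusted p = 0.694). The contractile list (mean -0.02, camera adjusted p = 0.0482; adjusted p = 0.868 with an estimated correlation) and the cardiac transcription factors (mean -0.03, adjusted p = 0.0045; adjusted p = 0.449 with an estimated correlation) ranked below other genes in males, with 0 members past the test over all probe sets or adjusted over the list alone. The contractile list also moved with the NHR arrays apart, which include more females than males. Whether that gives its lower rank in males was not tested. Median, mean and test differed in sign for 7 uncalled lists (fetal, calcium handling, cell cycle, endothelial, atrial, growth factor and heart mass).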

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

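The test of signal compression, that of a different share of cell types and that of more atrial tissue were chosen only after the results they address had been seen, as was leaving out the NHR arrays apart.

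Bmp10 and Edn1 differed between the sexes in their response to strain when the adjustment covered only the 74 named genes. Most of the 74 were named for strain differences on these same arrays, so this smaller set was not chosen independently of the data. With all 16 arrays neither gene passed the interaction test over all probe sets. The strain difference in males minus that in females was -1.38 for Bmp10 (adjusted p = 6.6e-04 over the named genes, 0.243 over all probe sets) and -1.06 for Edn1 (0.00549 and 0.676). Both genes were higher in HHR than in NHR females on 4 of 4 arrays. The fetal and hypertrophy list (adjusted p = 2.3e-04, median -0.12) and the atrial list (adjusted p = 0.00518, median -0.06) were also apart between the sexes by camera, but not with an estimated correlation (adjusted p = 0.688 for both). Nppa belongs to both lists and Bmp10 to the atrial list, so these results are not independent of each other.

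The higher Bmp10 and Kcnj3 in HHR could come from more atrial tissue in the HHR pieces, from a larger share of trabecular and conduction tissue, or from regulation within the ventricle, which was not tested here. Kcna5, an atrial channel gene, was lower (-0.34), and Myl7, abundant in atria and at a mean level of 12.92 here, differed by 0.07 with a 95% upper bound of 0.23, below the Kcnj3 difference of 0.57. The interval of Sln (mean level 8.52) ran from -0.40 to 1.09, so atrial tissue cannot be told apart from the other explanations. The 10 trabecular and conduction genes averaged 0.05 higher in HHR (exact two-sided permutation p = 0.0632, 95% upper bound 0.106), with 3 genes higher (Id2, Irx5 and Sema3a) and Tbx3 lower, which leaves that explanation open too.

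Genes called for strain lay beside each other in the genome order of assembly GRCr8 more often than in shuffled orders: for 25.97% of 3300 called genes the next tested gene was called too, against a median of 23.1% and a highest value of 25.74% in 10000 shuffles. For the 126 genes called at least 1.5-fold the share was 3.97%, against a median of 0.794% in the shuffles, 53 of which reached it, and 0.8% for as many variable genes, but it rests on 5 pairs. Among these, Psmb9 with RT1-DMb and RT1-DMb with RT1-DMa share a gene and are not independent. Both genes changed in the same direction in 3 of the 5 pairs, and in 471 of the 856 pairs among the 3300. Neighbours alike in the first 3 letters of their names do not account for this in the 3300 genes as a whole. Without them the share was 26.7%, above the highest shuffle (25.9%), and for the 126 it was 3.51% (reached by 146 shuffles). Families with unlike names were not removed and the sharing of probes was not examined, so families that share probes stay open. Blocks of sequence inherited differently by the strains could give this pattern, but for the 3300 an equal number of genes with the largest variation within groups gave 25.41%, a margin under 2 SDs of the shuffles (0.635) that was asked for after the value was seen, so inherited blocks cannot be told apart there from a clustering that any variable genes show, and the 126 hold too few pairs to decide. Sequence variants under the probes stay open, because among genes with a probe set changed at least 1.5-fold only Rpl22 had another of different values to compare (100% in the same direction, exact 95% lower bound 2.5%).

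NHR female 3, NHR female 4 and NHR male 4 lay apart from the other NHR arrays, with higher Zbtb16, Sult1a1 and Hif3a and lower Prnd and Cdc20 along that component. Of a list of 20 glucocorticoid-responsive genes written before the test, 18 were measured, 12 with a loading above 0 and 6, among them Dusp1 and Angptl4, below, and their mean loading exceeded 99.97% of 10000 random lists, which a stronger glucocorticoid signal in those hearts could give. That percentile is not particular to this list, since 8 of the 23 fixed lists lay outside the 1st to 99th percentile too, Dusp1, Mt2A and Pdk4 belong to other lists here, and random lists ignore the correlation between genes. A different share of cell types cannot be told apart: 3 of the 8 lists of other cells and tissues (endothelial, leukocyte and erythroid) lay above the 99th percentile, but their brightest members Cdh5 (11.36 to 11.44 against 11.51 to 11.61 on the other NHR arrays) and Fcer1g (8.45 to 8.61 against 8.85 to 9.10) were lower in the arrays apart, and Hbb (12.05 to 12.61 against 11.84 to 12.43) overlapped. Nor can compression of the signal by array or RNA quality, with a Spearman correlation of loading and expression of -0.248 across probe sets, and no biological explanation given by the groups was tested. The scores along the component also followed the replicate number in each of the 4 groups, HHR included. Processing batches were not given, so a batch shared by arrays of the same number cannot be told apart either.

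Single arrays were flagged within their group of 4 in 19 of 296 tests of named genes (6.42%), where chance alone would give about 14.8 (5%), with 7 in HHR groups and 12 in NHR groups. The value for each is its gap to the nearest array divided by the range of the group. A high value can come from a small gap where the other 3 arrays nearly coincide. Slc2a1 in NHR female 3, at 11.69 against 11.71 on each of the others, and Myh7 in NHR female 1, at 13.51 against 13.57 to 13.59, are of this kind. In NHR female 3 the low Trim55 (0.843), Slc2a1 (0.835) and Nppb (0.852) and the high Ndufa10 (0.841) were flagged. In NHR male 4 it was the low Mcm5 (0.838), Pgam2 (0.835) and Hey2 (0.857). Other NHR values were a low Zfp347 in female 4 (0.896), a low Ttr in female 2 (0.830), a low Myh7 in female 1 (0.846), a high Med22 in male 2 (0.830) and a high Trim55 in male 3 (0.863). In HHR male 4, Akr1b10 was low (0.953) and Slc2a1 high (0.882). In HHR female 4, Cxxc4 was high (0.932) and Hbb (0.929) and Dusp1 (0.924) low. Akr1c14 was low in HHR female 1 (0.833) and Rpl22 high in HHR female 3 (0.831). The widest of these were Nppb in NHR female 3, at 11.95 against a mean of 12.76 on the other 3 arrays, and Akr1b10 in HHR male 4, at 9.39 against 10.09.

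The arrays were also split in other ways. For the strain comparison 1 of 100 splits (the real one, 5651 probe sets) gave as many calls, and the highest other gave 893. Within males (1098 against 2) and within females (3278 against 0) it was 1 of 35 splits each. These counts argue against a chance assignment of single arrays. Litters and batches are not given, so the splits cannot exclude a difference between litters or batches. The real strain difference also adds spread within the groups of the other splits, which can lower their counts. For the interaction the real count was 0, which all 100 splits reach by construction (highest other 7), so the splits say nothing about chance there. For the sex comparison 2 of 100 splits reached its 3 calls. The highest other gave 79, with all 3 NHR arrays apart on the same side. Within NHR that split set replicates 3 and 4 of both sexes against replicates 1 and 2. Within HHR it did not follow the replicate number. So many calls point to a structure of the arrays, but whether the NHR arrays apart or the replicate number account for it was not tested.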

How the results depend on the processing

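The list tests without each array in turn and the results without the NHR arrays apart were chosen only after the data were seen. The count for strain moved from 5651 to 2893 at an adjusted p under 0.01 and to 229 at 1.5-fold or more, and lay between 4651 and 6402 without any 1 array. Without the NHR arrays apart it was 3997, of which 3363 were among the 5651. In males the 1098 calls became 2035 with array weights, 332 under 0.01 and 200 at 1.5-fold, and 489 to 2026 without any 1 array. In females the 3278 became 1176 under 0.01, 334 at 1.5-fold and 1238 without the NHR arrays apart (939 shared), and 1830 to 3761 without any 1 array. The interaction gave 0 to 1 calls without any 1 array and 0 under the other alternatives. The 3 calls for sex became 5 with array weights and 0 under 0.01, at 1.5-fold and without the NHR arrays apart, and 2 to 4 without any 1 array. The smaller counts at stricter thresholds follow from the thresholds. For the others the cause was not tested, and fits with fewer arrays also have less power.

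Of the 5 lists called for strain, 0 were called with an estimated correlation and 3 with the replicate block, which ended the calls of the calcium handling and atrial lists (adjusted p = 0.0539 for both). Without any 1 array 3 to 5 were called. The count was 3 without HHR male 4, NHR female 1, NHR female 2, NHR male 1 or NHR male 2. The cell cycle list was lost with fry (adjusted p = 0.209) and without the NHR arrays apart (0.0536). The atrial list was lost after quantile normalization (0.0919), median centring (0.0516) and cyclic loess (0.147). Cardiac transcription factors were gained with fry (0.0122), quantile normalization (0.0233), cyclic loess (0.0166) and without the NHR arrays apart (0.00674, within 0.00674 to 0.667), and the heart mass list with fry (2.5e-04, within 2.5e-04 to 0.667). The endothelial list was gained with fry (0.00257), quantile normalization (0.0233) and cyclic loess (0.0208). The 5 called lists kept their direction under the alternatives run, and 8 uncalled lists changed direction in at least 1 of them, such as the mural list without the NHR arrays apart (mean 0.02 to -0.02).

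Of 72 genes named for strain, 69 passed, and 67 to 69 did so without any 1 array. Over 1727 pairs of gene and alternative, 1700 kept their side of the threshold and direction, 26 lost the call (Ttr, Myog, Notch3 and Myh7), 1 gained it (Atp2a2 after cyclic loess, adjusted p = 0.00804, range 0.00804 to 0.333) and 0 reversed. Most of these genes were named for large changes or small p in the same data, and the alternatives reuse most of the arrays. Their calls were thus likely to be kept, which says little about the other calls. Myog was removed by the filter on dim probe sets, so it has no value there. The replicate numbers were not taken to pair the arrays, and the main fit has no block for them. Of 24 pairs with the same number, 11 had residuals correlated above 0.1, the lowest at -0.108. Their median correlation was 0.0905, against -0.0302 for pairs with other numbers, and 9 of 16 arrays correlated best with their own number. The leading component within groups also followed the number in each group. Arrays of the same number thus shared some structure, which the main fit leaves in the spread within groups. With the replicate block the counts were 6145 for strain, 1639 in males, 3874 in females, 0 for the interaction, 3 for sex and 3 for the lists. Array signal over background was not analysed here, so it is open which dim probe sets carry no signal.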

Other observations

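The limma values in this part were put together after they had been seen, whereas the permutation tests on held-out S phase and G2 and M phase genes were written before their results were seen, although the pattern they address had been seen.

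The parts of ribonuclease P did not move together. Beside the lower Pop5 (-1.28) and Rpph1 (-0.80), the subunits Rpp25 (0.34, limma adjusted p = 9.7e-04), Pop4 (0.25, adjusted p = 0.00239) and Rpp38 (0.21, adjusted p = 0.0319), chosen after their values were seen, were higher in HHR. Of the neuregulin pathway, the ligand Nrg1 was higher (0.79) and its receptor Erbb4 lower (-0.30), while the partner receptors Erbb2 (-0.02, adjusted p = 0.818) and Erbb3 (0.04, adjusted p = 0.772) did not pass the test. The Psmb9 gene and its neighbours RT1-DMb (0.74, limma adjusted p = 4.9e-07) and RT1-DMa (0.63, adjusted p = 6.9e-08) in the class II region, chosen after their values were seen, were higher together, while RT1-Da (-0.50) and Cd74 (-0.32), also of class II presentation, were lower. Of the glucocorticoid-responsive genes, Dusp1 (0.52) and Mt2A (0.21) were higher in HHR and Cdkn1c (-0.37), Angptl4 (-0.43) and Pdk4 (-0.17) lower, so the list did not move in 1 direction between the strains.

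In the cell cycle list, of which 28 of 39 members did not pass, genes of replication such as Ccne1 (0.60), Prim1 (0.66) and Mcm5 (0.52) were higher in HHR and the mitotic cyclin Ccnb2 (-0.26 and -0.28 on its 2 probe sets) lower. The list was not divided beforehand, and a shift from mitotic towards S phase transcripts, which this may reflect, is a hypothesis that came from these data. Among held-out genes, 19 S phase genes averaged 0.16 higher in HHR (exact two-sided permutation p = 0.00575; 0.10 without the NHR arrays apart), with 6 higher, such as Chek1 (0.66) and Exo1 (0.40), and Rfc2 lower (-0.17). The 20 G2 and M phase genes differed by -0.02 (exact p = 0.808), with 0 higher and 2 lower (Tacc3, -0.34, and Kifc1, -0.18). The S phase mean minus the G2 and M phase mean was higher in HHR by 0.18 (95% interval 0.09 to 0.27, exact two-sided permutation p = 0.00109 over 12870 splits), with 7 of 8 HHR arrays above the highest NHR array. It was 0.11 in males and 0.25 in females, and 0.15 without the NHR arrays apart, in which the cell cycle list was low. The S phase mean was higher by 0.18 in males and 0.15 in females, while the G2 and M phase mean differed by 0.06 and -0.10. Over both sexes the score therefore rests mainly on higher S phase genes, and a fall of mitotic transcripts was not shown. The held-out genes were measured on the same arrays as the pattern and cell cycle genes vary together, so they are not independent evidence. The arrays hold a mixture of cells, so which cells carry the higher S phase transcripts stays open.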
